A study of Homo sapiens with 16 samples.

How the data were processed

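Regulatory T cells were sorted from the peripheral blood of healthy people as CD4+CD25highCD127neg cells, per the labels' protocols. The cells were stimulated for 4 hours with PMA (phorbol ester, 30 ng/ml) and ionomycin (a calcium ionophore, 150 ng/ml). At hour 3 an interferon gamma capture reagent was added, and after 45 minutes the cells were sorted again into those that held captured interferon gamma (IFNg_pos) and those that did not (IFNg_neg). RNA was amplified from 50 ng of total RNA and hybridised to Affymetrix HG-U133 Plus 2 arrays. Each of the 16 libraries was 1 array, 8 in each group, with replicate numbers 1 to 8 in both. Nothing in the labels says whether a number marks a donor, or whether the 8 libraries of a group come from 8 people, so the p-values measure only the spread between these libraries.

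The deposited values are on the log2 scale, and the authors made them with affy and RMA, per the submitters' processing notes, which also name limma. RMA corrects background, applies quantile normalization to probes and summarises probes into probe sets. Versions, settings and the design of any fit are not given in the sources used here. Values came from the series' value table, which has 1 column per sample. A second deposited table pairs probe sets with gene symbols. Its 16 columns of values carry names that match no sample's labels and were not used, although the plan had named that table as the source of values.

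Of the 54675 probe sets, 41226 had exactly 1 gene symbol and 13449 had none that could be used, among them 67 cells that a spreadsheet had turned into dates. Of the 19918 symbols, 17045 were current, 1445 were updated through a unique synonym, and 1428 matched nothing in the gene name table and kept the name in the file. The probe set with the highest mean over the 16 arrays stood for each gene, which gave 19889 genes. Genes whose probe set had a mean log2 value below 3.792, the 0.333 quantile of all probe sets, were left out, so that 15641 genes were tested. Where values of a named gene lay below that cutoff, its change was also computed with those of the group with the lower mean raised to it, as a bound chosen after the data were seen, which is printed where at least 4 libraries of a group lay there. No genome coordinates are given because no build is named. For arrays the precision is limited by their number, and dim probe sets carry background signal as well as transcript.

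The comparison was IFNg_pos minus IFNg_neg, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no block and two-sided. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and a change of at least 2-fold meant an absolute log2 change of at least 1. Adjusted p-values of genes are limma's throughout, and those of lists are from limma's camera, adjusted over the 29 lists. IFNG was also tested with an exact permutation test of the group labels. The group fit, the filter, the 29 gene lists, the rule for named genes and the alternatives for the 16 libraries were chosen before the data were examined. The fit without the pair of libraries numbered 8 was chosen after seeing the data, for the reason given with the IFNG values, and so was every alternative to it. No library was moved to another group.

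The 29 lists were the Th1, Th2, Th17 and Tfh programs, T cell cytokines, chemokines, a Treg signature, naive and resting T cell genes, the PI3K AKT mTOR pathway, FOXO factors and targets, immediate early and activation genes, cytotoxic genes, type I interferon response, interferon gamma response, coinhibitory, costimulatory and trafficking receptors, TGF beta signalling, apoptosis and survival, glycolysis, oxidative phosphorylation, cholesterol synthesis, cell cycle, heat shock and handling stress, ribosomal proteins, and markers of monocytes and dendritic cells, of B cells, of NK and CD8 T cells, and of platelets and erythroid cells. IFNG is in none of them. Camera used a preset correlation between genes of 0.01, with an estimated correlation as an alternative and fry, a test of whether a list's genes move one way, beside it. A list's genes were also adjusted over the list alone.

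The rule for named genes took IFNG, the 10 genes with the largest rise and the 10 with the largest fall among those that passed, up to 4 members per list with the largest change among those that passed, and a fixed set of T cell and lineage genes whatever their values. Genes of the Y chromosome and XIST were left out of the 10 per direction. Some genes that the rule names are not reported one by one. They were left out of the search for values that stand apart and of its counts, after that search had first been run with them, while counts of genes in tests and lists include them.

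Alternatives were the replicate number as a fixed or random block, no filter or a filter at the 0.5 quantile, the mean of a gene's probe sets or every probe set on its own, quantile normalization again, centring of each array on its median, eBayes with a trend and robust prior, array weights, leaving out each library in turn, and the other list tests. The fits were tested on simulated data made from the real genes and groups, with 100 genes changed by a log2 value of 1 and 100 by 2. With 14 libraries 67% and 81% of these were recovered, with 17 false calls among 165. With 16 libraries 60% and 83% were recovered, with 7 false calls among 150. When 1 simulated pair was exchanged between the groups of 16, the recovery was 0% and 2%.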

Results

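The deposited data hold expression arrays of human regulatory T cells (Tregs) that were stimulated with PMA and ionomycin and then sorted by whether they secreted interferon gamma. The group IFNg_pos has 8 libraries and the group IFNg_neg has 8. The median log2 value of an array lay between 4.666 and 4.794.

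The comparison asks how Tregs that secrete interferon gamma, and so share a feature of Th1 effector cells, differ in expression from Tregs of the same stimulation that do not. The IFNG transcript (chromosome 12) checks the sort, because the cells were divided by the captured protein. In the libraries labelled IFNg_pos 1 to 7 its log2 value lay between 13.09 and 13.66, and in those labelled IFNg_neg 1 to 7 between 3.897 and 6.301. The library labelled IFNg_pos 8 had 5.938, below all 7 others of its label, and the library labelled IFNg_neg 8 had 13.599, above all 7 others of its label. Over all 16 libraries as labelled, IFNG was 12.42 ± 2.63 (SD, n = 8) in IFNg_pos and 6.34 ± 3.07 (SD, n = 8) in IFNg_neg. This difference of 6.08 had an exact permutation p of 0.00497 (two-sided, 12870 arrangements) and a limma adjusted p of 0.0585. Without the pair of libraries numbered 8, IFNG was 13.34 ± 0.223 (SD, n = 7) against 5.303 ± 0.979 (SD, n = 7), a difference of 8.04 ± 0.36 (SE) with a limma adjusted p of 2.69e-08. Because this pair was left out for its IFNG values, these numbers describe the other 14 libraries and are no independent test of the sort.

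With all 16 libraries as labelled, 17 genes fell in IFNg_pos and 0 rose by limma, of which 16 changed at least 2-fold, and 4123 genes had an unadjusted p under 0.05. The largest falls included HELQ (-2.30 ± 0.36, SE), a DNA helicase, PSMD10 (-2.19 ± 0.38) and INSIG2 (-2.03 ± 0.35), each with an adjusted p of 0.0442. The others of the 10 largest measured falls were LRTOMT (-2.04), MTRFR (-1.70), SCOC (-1.67), TIGIT, NSMCE2 (-1.47), WDR5B and ATP6V0A4. Values below the filter's cutoff of 3.792 were found in 6 of 8 IFNg_pos libraries for WDR5B and in 7 for ATP6V0A4, which fell by at least 1.54 and 1.07 with such values raised to the cutoff, so their places are not settled. TIGIT, a coinhibitory receptor and Treg marker, was the only member of any list that passed (-1.49 ± 0.25, adjusted p = 0.0442). Among lists, 13 of 29 passed camera, 5 of them upward, and 0 passed with an estimated correlation. Other splits of the same 16 libraries passed a median of 4 lists with the preset. These results rest on groups in which IFNG goes against the label of 1 library each.

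Without number 8, 4273 of the 15641 genes passed (27.3%), of which 2449 rose and 1824 fell in IFNg_pos. The 17 genes of the 16-library fit all passed with the same sign. At least 2-fold changes were mostly falls, with 1094 down and 222 up. In 569 genes all 7 IFNg_pos libraries lay above all 7 IFNg_neg libraries and in 449 genes below, together 6.51% of genes where chance gives 0.0583%. The median log2 change over all genes was 0.119. All results that follow are from these 14 libraries, as a fit chosen after seeing the data.

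**Figure D1:**
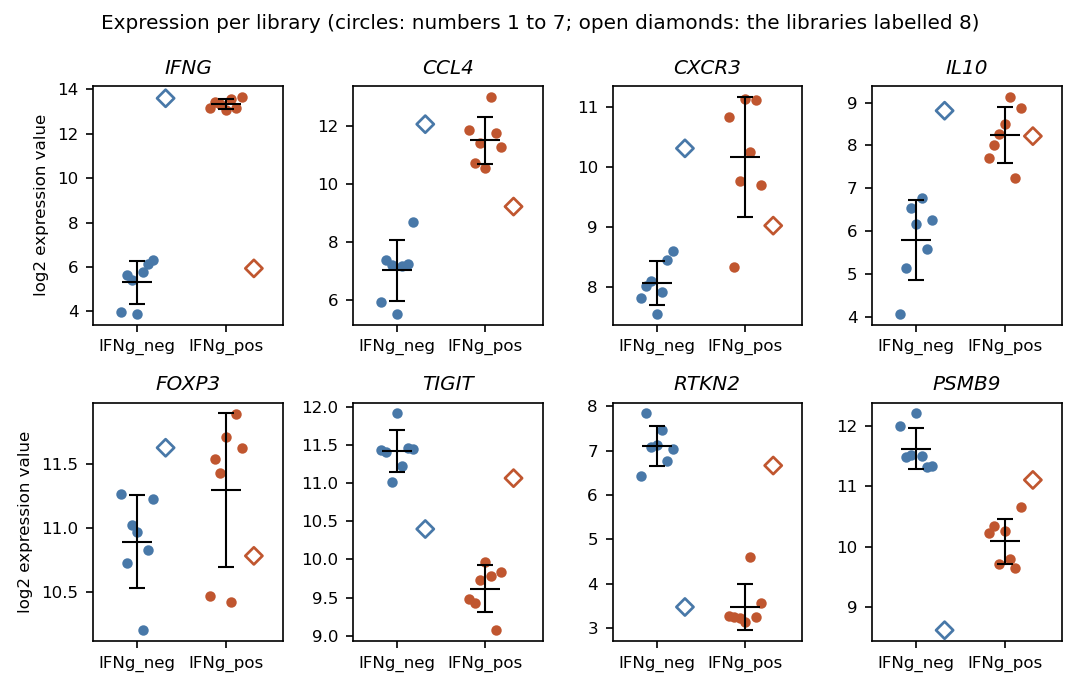
Log2 expression values of IFNG, CCL4, CXCR3, IL10, FOXP3, TIGIT, RTKN2 and PSMB9 in each library labelled IFNg_neg or IFNg_pos, with circles for numbers 1 to 7, black bars for their mean ± SD (n = 7) and open diamonds for the libraries labelled 8. IFNG lies at 13.09 to 13.66 in IFNg_pos 1 to 7, while the diamond labelled IFNg_pos stands at 5.938 and the diamond labelled IFNg_neg at 13.599.

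The secreting cells expressed more of many effector mediators than the cells that did not secrete interferon gamma. CCL4 rose most after IFNG, by 4.48 ± 0.47 on the log2 scale (SE, n = 7 per group, adjusted p = 0.000153), and lay above the other group in all 7 libraries. CCL5 rose by 2.66, and the Th1 chemokine receptor CXCR3 by 2.09 ± 0.38 (adjusted p = 0.00354). The rise was not limited to Th1 products: IL3 (3.22 ± 0.68, adjusted p = 0.0074), IL4 (2.70), IL10 (2.45), IL21 (2.44), IL22 (2.37), IL17A (1.94) and IL2 (1.67) rose too. Of the lineage factors BCL6 rose by 1.82 on its main probe set, while its other probe sets did not pass (1.31 and 0.33). TBX21 (1.04, adjusted p = 0.054) and GATA3 (0.40, adjusted p = 0.14) did not pass. TNF (0.54, adjusted p = 0.223, and 0.35 without IFNg_neg 1), STAT4 (0.03, adjusted p = 0.929) and IL12RB2 (-0.92, adjusted p = 0.0766) did not pass either. TBX21 passed without IFNg_neg 3 (1.18, adjusted p = 0.0449) or IFNg_pos 1 (1.18, adjusted p = 0.0425), and IL12RB2 without IFNg_pos 2 (-1.12, adjusted p = 0.0404) or IFNg_pos 3 (-1.15, adjusted p = 0.0298).

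As a list, T cell cytokines shifted upward (camera adjusted p = 0.0154), with 13 of 30 up, 0 down by limma (1 at an unadjusted p under 0.05) and 17 not passing, and 13 up adjusted over the list alone. The call was lost at an adjusted p of 0.267 with an estimated correlation. Chemokines passed upward (adjusted p = 0.0442, and 0.255 with an estimated correlation), with 3 of 12 up, 0 down by limma (0 at an unadjusted p under 0.05) and 9 not passing, and 4 up adjusted over the list alone. This call was lost with no filter (adjusted p = 0.157), quantile normalization again (0.075) and array weights (0.0722), and without IFNg_neg 4 or IFNg_pos 1, 3 or 6 (0.0527 to 0.0719). Cytotoxic genes passed upward as well (adjusted p = 0.0239, and 0.249 with an estimated correlation), with 6 of 24 up, 1 down and 17 not passing. Adjusted over the list alone, 10 were up and 1 down. GNLY (1.89), GZMB (1.89) and FASLG (1.60) rose, and CTSW (-0.91) fell. Of the NK and CD8 T cell markers 4 of 9 rose in the same fit and 0 fell by limma (0 unadjusted), CD160 (1.59), ZBTB16 (1.08), NCAM1 (0.47) and NCR1 (0.41), although that list did not pass (adjusted p = 0.102). Its median (0.41) did not stand apart from those of equally bright genes either. The Th1 program as a whole did not pass camera (adjusted p = 0.959), with 5 of 22 up, 3 down and 14 not passing. It passed upward with fry (adjusted p = 0.0256), which does not compare a list with other genes. Adjusted over the list alone, 6 were up and 4 down. Its members CCL4, CCL5 and CXCR3 rose, and IL12RB1 (-1.76) fell on the main probe set while 2 other probe sets of it did not pass (0.11 and -0.06).

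Treg identity genes were divided. The core genes FOXP3 (0.40, adjusted p = 0.223), IL2RA (0.31, adjusted p = 0.17) and CTLA4 (-0.01, adjusted p = 0.94) did not pass and had mean log2 values of 11.295, 11.939 and 13.099 in IFNg_pos, although IL2RA passed without IFNg_pos 1 (0.44, adjusted p = 0.0328). A pair of other FOXP3 probe sets passed upward (0.42 and 0.76). RTKN2 had a fitted fall of 3.64 ± 0.25 (SE, n = 7, adjusted p = 2.15e-06), but 6 of 7 IFNg_pos libraries lay below 3.792, and with these raised to it the fall was at least 3.20. TIGIT fell by 1.80 ± 0.16 (adjusted p = 2.78e-05). LAYN (-2.89), ZC2HC1A (-2.21) and LRRC32 (-1.40) fell as well. RTKN2 and TIGIT were lower in all 7 IFNg_pos libraries than in any IFNg_neg library. IKZF2, which encodes Helios, was also lower in all 7 but did not pass on the main probe set (-1.96 ± 0.72, adjusted p = 0.0552), while 2 other probe sets of it passed (-1.46 and -1.61). The main probe set had 5.646 in IFNg_pos 1, and passed without that library (-1.21, adjusted p = 0.00418) or without IFNg_pos 7 (-2.18, adjusted p = 0.0423). F5 rose by 2.24. The Treg signature passed downward (adjusted p = 0.0239, 0.0876 with a stricter filter, and 0.414 with an estimated correlation), with 3 of 40 up, 9 down and 28 not passing, and 3 up and 9 down adjusted over the list alone.

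Most genes of resting T cells and of the PI3K, AKT and FOXO axis did not pass, and among those that did more fell than rose. PIK3IP1, an inhibitor of PI3K, fell by 1.79 ± 0.29 (SE, n = 7, adjusted p = 0.00209) and was lower in all 7 libraries. The kinase genes PIK3CG (-2.18) and PIK3CA (-1.20) fell as well, while AKT1 (0.42, adjusted p = 0.473, and 0.16 without IFNg_neg 6, 0.19 without IFNg_pos 2 and 0.755 without IFNg_pos 1) did not pass. AKT2 did not pass on its main probe set (-0.18, adjusted p = 0.701). Another AKT2 probe set passed downward (-0.76, adjusted p = 0.0288), and its remaining ones did not pass (-0.52 to 0.40). The PI3K AKT mTOR list did not pass (adjusted p = 0.0643), with 2 of 45 up, 7 down and 36 not passing, and 2 up and 6 down adjusted over the list alone. Of the FOXO genes, FOXO1 (-0.29, adjusted p = 0.24, and -0.175 without IFNg_pos 1) and FOXO3 (-0.83, adjusted p = 0.321) did not pass. FOXO3 had 10.343 in IFNg_pos 6, and passed without that library (-1.39, adjusted p = 0.033), while it was at -0.51 without IFNg_pos 5. Of the FOXO targets, CDKN1B (-1.84) fell. On the main probe set only, BNIP3 (-1.61) passed downward and BCL6 (1.82) upward. FOXO factors and targets passed downward (adjusted p = 0.0278, and 0.102 with an estimated correlation), with 1 of 29 up, 6 down and 22 not passing, and 1 up and 6 down adjusted over the list alone. Naive and resting T cell genes passed downward (adjusted p = 0.0239, 0.0727 with a stricter filter, and 0.102 with an estimated correlation), with 3 of 27 up, 7 down and 17 not passing, and 3 up and 9 down adjusted over the list alone. MAL (-1.93) and SCML1 (-1.75) fell, while CCR7 (-0.04, adjusted p = 0.916) did not pass.

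Interferon-responsive genes were lower in the cells that secreted interferon gamma. PSMB9 fell by 1.53 ± 0.19 (SE, n = 7, adjusted p = 0.00045) and was lower in all 7 libraries, and GBP4 (-2.02) fell too. GBP3 fell by at least 1.53 (adjusted p = 0.0102), computed with the values of 5 of 7 IFNg_pos libraries below 3.792 raised to it. The interferon gamma response list passed downward with the preset (adjusted p = 0.000426) and the estimated correlation (adjusted p = 0.0165), with 1 of 30 up, 12 down and 17 not passing, and 1 up and 12 down adjusted over the list alone. The type I interferon response list passed downward (adjusted p = 2.91e-06, and 0.102 with an estimated correlation), with 1 of 27 up, 10 down and 16 not passing, and 1 up and 12 down adjusted over the list alone. IFIT1 (-2.43), EPSTI1 (-2.03), HERC5 (-1.94) and SAMD9L (-1.89) fell.

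Respiratory chain genes fell without exception among those that passed. The oxidative phosphorylation list passed downward with the preset (adjusted p = 2.08e-09) and the estimated correlation (adjusted p = 0.0338), with 0 of 34 up by limma, 17 down and 17 not passing, and 21 down adjusted over the list alone. At an unadjusted p under 0.05, 0 were up and 21 down. NDUFB5 (-1.63), NDUFV2 (-1.42), ATP5MC1 (-1.26) and SDHD (-1.25) fell most. Cholesterol synthesis passed downward (adjusted p = 0.0442, and 0.102 with an estimated correlation), with 2 of 22 up, 6 down and 14 not passing, and 3 up and 7 down adjusted over the list alone. This call was lost with the stricter filter (adjusted p = 0.131), the mean of probe sets (0.0568) and quantile normalization again (0.0907), and without IFNg_neg 1, 2 or 5 or IFNg_pos 2, 4, 6 or 7 (0.0519 to 0.0615). SC5D (-2.05), NSDHL (-1.55) and FDPS (-1.16) fell. Ribosomal proteins passed downward by small amounts (adjusted p = 0.00119, 0.129 with the mean of probe sets, and 0.255 with an estimated correlation), with 0 of 26 up by limma (1 at an unadjusted p under 0.05), 6 down and 20 not passing, 6 down adjusted over the list alone, and RPS9 (-0.62) the largest fall.

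**Figure D2:**
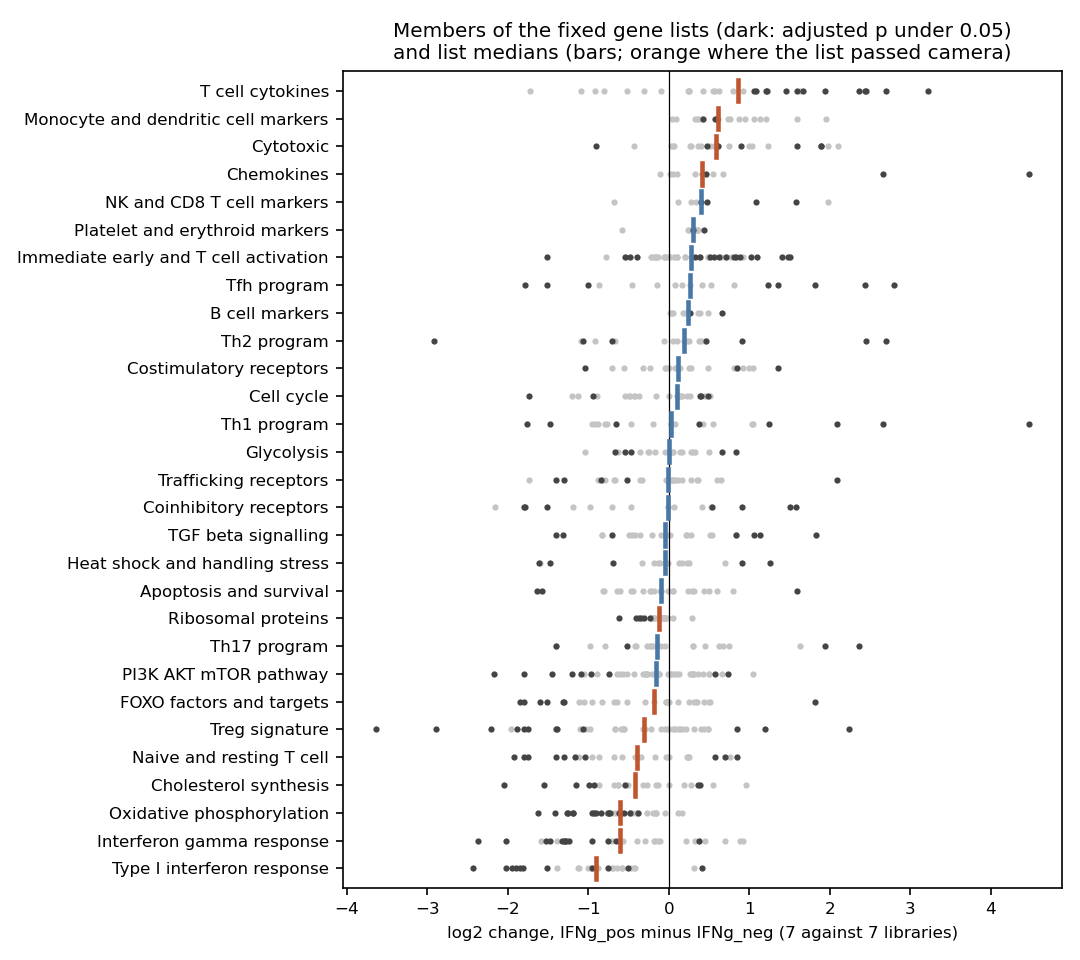
Log2 change (IFNg_pos minus IFNg_neg, 7 against 7 libraries) of each member of the 29 fixed gene lists, dark where the adjusted p was under 0.05 and grey otherwise, with a vertical bar at each list's median, orange where the list passed camera and blue where it did not. The medians run from -0.90 for the type I interferon response to 0.86 for T cell cytokines.

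The 10 largest rises were IFNG, CCL4, LOC100190986 (3.43), TCOF1 (3.38), IL3, LOC399491 (3.06), PGGHG (2.99), TTN (2.94), NPIP (2.94) and SPEN (2.84). LOC399491 and NPIP belong to a family of near-identical copies whose probes may bind several members, so their identity is uncertain. The 10 largest measured falls were TNFSF13B (-3.70), SYT4 (-3.69), RTKN2, NTAN1 (-3.22), RAB33B (-3.14), C1orf56 (-3.10), GPATCH2 (-3.10), TMEM154 (-3.06), STRADB (-3.05) and RABGAP1L (-3.02). The falls are fitted sizes, and their order is not settled, because values in IFNg_pos lay below 3.792 in 6 of 7 libraries for TNFSF13B and RTKN2, 5 for GPATCH2, 4 for TMEM154, 2 for C1orf56, STRADB and RABGAP1L and 1 for NTAN1 and RAB33B. TNFSF13B, which encodes the B cell factor BAFF and had a mean log2 value of 6.843 in IFNg_neg, fell by at least 2.73 with such values raised to 3.792, GPATCH2 by at least 2.68 and TMEM154 by at least 2.63. Tested on their own, the other probe sets of C1orf56 (-0.88 and -0.06) and GPATCH2 (-0.31) did not pass. For RABGAP1L (-0.35 and -0.12), TTN (0.24 and 0.59) and TCOF1 (0.11) some did not pass, while another passed the same way. All other probe sets of NTAN1, TNFSF13B, SPEN, LOC100190986 and LOC399491 passed the same way.

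Small changes differed in direction between dim and bright genes. With genes cut into 6 bins by mean expression, the median log2 change was 0.27, 0.29 and 0.26 in the 3 dimmest bins, 0.01 in the 4th, -0.39 in the 5th and -0.29 in the brightest. In the dimmest bin alone 550 genes rose and 62 fell, against 160 and 671 in the brightest. Among changes of at least 2-fold, falls outnumbered rises in every bin, from 43 against 3 in the dimmest to 199 against 65 in the brightest. After quantile normalization again, the medians of the dimmest and brightest bins were 0.21 and -0.15. The IFNg_pos arrays were also more variable, with a median SD per gene of 0.446 against 0.281 (n = 7 each) and the larger SD in IFNg_pos for 80% of genes. Each list's median was therefore set against 10000 random lists of the same size matched on mean expression. The random lists hold unrelated genes. Their central 95% may be too narrow for lists whose members move together, such as monocyte markers (estimated correlation 0.594). The medians of T cell cytokines, chemokines, cytotoxic genes, immediate early genes, the Th2 and Tfh programs, costimulatory receptors and monocyte markers lay above the central 95% of the random lists, and those of both interferon responses and oxidative phosphorylation below it. The Treg signature (15% of random lists lower), naive and resting genes (9.09%), FOXO factors and targets (38.7%), cholesterol synthesis (5.83%) and ribosomal proteins (62.6%) lay within it, so their medians did not stand apart from those of equally bright genes. The same held for the markers of NK and CD8 T cells (95.4%), B cells (39.2%) and platelets and erythroid cells (72.6%).

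**Figure D3:**
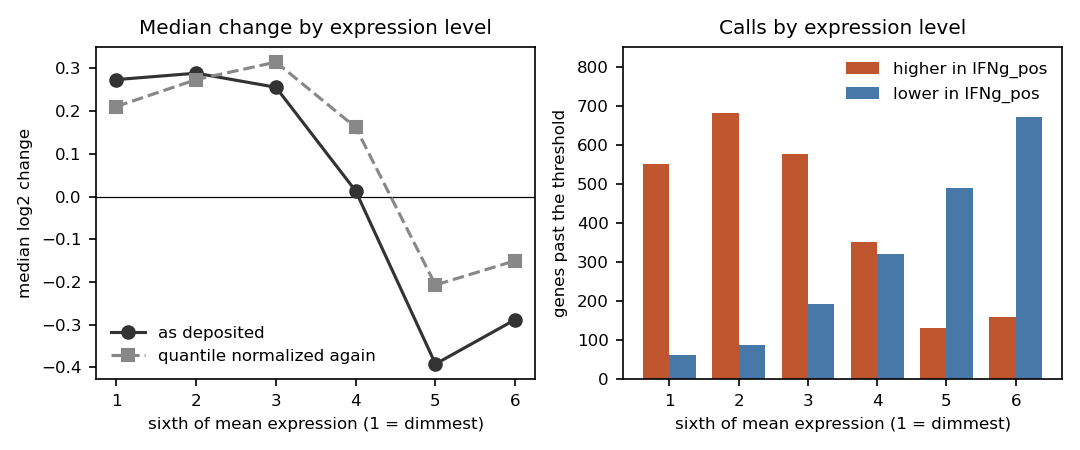
Left, median log2 change (IFNg_pos minus IFNg_neg, 7 against 7 libraries) of genes in 6 bins of mean expression, from the dimmest (1) to the brightest (6), as deposited (solid) and after quantile normalization again (dashed); right, number of genes past the threshold that were higher or lower in IFNg_pos per bin. The deposited medians are 0.27 in bin 1, lowest in bin 5 (-0.39) and -0.29 in bin 6, with 550 genes up and 62 down in bin 1 and 160 up and 671 down in bin 6.

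Immediate early genes and the other helper programs changed in part. BHLHE40 rose by 1.41, NFKBID by 1.51 and NFATC1 by 1.48, while ATF3 fell by 1.51, and the immediate early and activation list did not pass (adjusted p = 0.163), with 14 of 45 up, 4 down and 27 not passing, and 16 up and 4 down adjusted over the list alone. The Tfh program did not pass (adjusted p = 0.549), with 5 of 17 up, 3 down and 9 not passing, and 6 up and 3 down adjusted over the list alone. Its members POU2AF1 (2.79), IL21 and, on the main probe set only, BCL6 rose and BTLA (-1.79) fell. The Th2 program did not pass (adjusted p = 0.565), with 4 of 19 up, 3 down and 12 not passing, and 4 up and 3 down adjusted over the list alone. Besides IL4 and IL10, which rose, IL1RL1 (-2.91), the receptor of IL-33, fell. The Th17 program did not pass (adjusted p = 0.549), with 2 of 22 up, 2 down and 18 not passing, and the same numbers adjusted over the list alone. IL22 and IL17A rose and CCR6 (-1.40) fell, so that the list's median (-0.15) and test were downward and its mean (0.09) upward.

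Surface receptors moved both ways within each class. The coinhibitory list did not pass (adjusted p = 0.335), with 4 of 17 up, 3 down and 10 not passing, and 5 up and 4 down adjusted over the list alone. CD160 (1.59) rose, while TIGIT, BTLA and TOX (-1.51) fell. Of costimulatory receptors (adjusted p = 0.717), 2 of 20 rose, 1 fell and 17 did not pass, with 1 up and 1 down adjusted over the list alone, and TNFSF8 (1.36) and CD28 (-1.04) were the largest changes. Of trafficking receptors (adjusted p = 0.192), 1 of 26 rose, 4 fell and 21 did not pass, with 1 up and 4 down adjusted over the list alone. CXCR3 was the one that rose, and S1PR1 (-1.30) and CXCR4 (-0.84) fell. In TGF beta signalling (adjusted p = 0.924), 4 of 24 rose, 3 fell and 17 did not pass, with 5 up and 3 down adjusted over the list alone. LTBP4 (1.83) and ID2 (1.13) rose and SMAD2 (-1.32) fell, and the list's median (-0.04) and test were downward while its mean (0.01) was upward.

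Markers of cells that the sort leaves out were compared as well. Monocyte and dendritic cell markers passed upward (adjusted p = 0.0239, 0.0598 with quantile normalization again, 0.0605 with fry, and 0.592 with an estimated correlation), with 3 of 19 up, 0 down by limma (0 at an unadjusted p under 0.05) and 16 not passing, and 3 up adjusted over the list alone. CD68 (at least 0.51 with the values of 4 of 7 IFNg_neg libraries below 3.792 raised to it), CLEC10A (0.58) and LILRA4 (0.43) rose, and CD14 (0.87, adjusted p = 0.134, and 0.42 without IFNg_pos 1) did not pass. The median of the 22 measured markers was 7.515 in IFNg_pos 1 and at most 5.073 in the other IFNg_pos libraries. The marker median in IFNg_pos 2 to 7 (4.146 to 5.073) overlapped that in IFNg_neg 1 to 7 (4.133 to 4.338). Without IFNg_pos 1, 3585 genes passed, and the list passed at an adjusted p of 0.0333. The random lists matched on mean expression were compared only with IFNg_pos 1 included. Whether the rise in the other libraries exceeds that of equally dim genes was therefore not tested. B cell markers did not pass (adjusted p = 0.0643), with 2 of 11 up, BLK among them (0.27, adjusted p = 0.0454), 0 down by limma (0 unadjusted) and 9 not passing, and 1 up adjusted over the list alone. NK and CD8 T cell markers did not pass (adjusted p = 0.102), with 4 of 9 up, 0 down by limma (0 unadjusted) and 5 not passing, and 4 up adjusted over the list alone, ZBTB16 (1.08) among them. Platelet and erythroid markers did not pass (adjusted p = 0.0807), with 2 of 10 up, 0 down by limma (0 unadjusted) and 8 not passing, and 2 up adjusted over the list alone. The medians of the B cell, NK and CD8, and platelet and erythroid lists did not stand apart from those of equally dim genes, which tended to rise. CD8A had a mean log2 value of 3.381, below the filter.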

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

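The tests of an exchange of libraries, of background signal and of myeloid RNA were chosen only after the results they bear on had been seen, and so was the fit of 14 libraries that the gene calls in this part come from. A value was picked out where the highest or lowest of the 8 libraries of a group stood apart, with a gap to the next library, as a share of the group's range, above Dixon's critical value at 95%. Of 280 such groups of values, 55 did so, and the numbers in parentheses are gap over range. Chance gives about 1 in 20 for independent values. That rate does not apply to the pair numbered 8, because most of these genes were named for differing between the other 14 libraries.

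The library labelled IFNg_neg 8 stood apart in 35 of the 55. It was the highest of IFNg_neg for the difference between 3' and 5' ACTB probe sets (0.708), the 25th percentile of the array (0.577), CD160 (0.79), CXCR3 (0.622), ID2 (0.55), IFNG (0.752), IL21 (0.628), LOC100190986 (0.78), LOC399491 (0.648), NPIP (0.66), PGGHG (0.562) and TTN (0.533). It was the lowest for the SD of the array (0.549), BTLA (0.565), CCR6 (0.58), CD28 (0.573), CDKN1B (0.546), DNAJB4 (0.697), FDPS (0.604), GBP4 (0.62), GPATCH2 (0.588), MAL (0.824), NDUFB5 (0.85), NDUFV2 (0.651), NTAN1 (0.667), PIK3CA (0.568), PIK3CG (0.833), PSMB9 (0.752), RAB33B (0.739), RPL11 (0.735), RPS9 (0.636), RTKN2 (0.675), SAMD9L (0.676), STRADB (0.613) and TNFSF13B (0.562). The library labelled IFNg_pos 8 stood apart in 9. It was the lowest of IFNg_pos for CCL5 (0.528), CD68 (0.536), IFNG (0.926), LOC399491 (0.71), MKI67 (0.635) and NPIP (0.744), and the highest for RAB33B (0.699), RTKN2 (0.582) and TIGIT (0.551).

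How often the other libraries stood apart cannot be set against the 1 in 20 that chance gives. Where a library of the pair described above stood apart, it widened the group's range, so that another could hardly do so. The values of the other libraries were scattered, apart from those of IFNg_pos 1, which had the highest CD14 (0.747) and monocyte marker median (0.685) and the lowest IKZF2 (0.752) of IFNg_pos. IFNg_pos 3 had the lowest CDKN1B (0.536) and the highest CTSW (0.566), IFNg_pos 4 the highest ZBTB16 (0.606), IFNg_pos 5 the lowest INSIG2 (0.545), and IFNg_pos 6 the lowest AKT2 (0.568) and the highest FOXO3 (0.527). IFNg_neg 2 had the lowest NCR1 (0.527), and IFNg_neg 4 the lowest difference between 3' and 5' GAPDH probe sets (0.659).

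The libraries numbered 8 ran against their labels in many genes beside IFNG. Of the 4273 genes called without them, 89.3% differed the opposite way between the pair, against 9.51% to 17.5% for numbers 1 to 7, each judged on genes called without its own pair. An incomplete sort, with both kinds of cells in each library, would put both between the groups, but on a scale from 0 (mean of the other IFNg_neg libraries) to 1 (mean of the other IFNg_pos libraries) the median gene was at 0.117 in the library labelled IFNg_pos 8 and at 0.975 in that labelled IFNg_neg 8. A candidate explanation is that the pair or its labels were exchanged, at the sort, on the arrays or in the deposit, which these values do not separate. No biological explanation was tested.

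Dim genes tended to be higher and bright genes lower in IFNg_pos. Of the difference of 0.562 between the dimmest and brightest bins, 64.2% was left after quantile normalization again (0.361). RMA had already applied this step to probes, so repeating it cannot decide whether normalization made the shift. Higher background signal on the IFNg_pos arrays may contribute, because all 27 bacterial control probe sets had a higher mean there, by a median of 0.252. For the oxidative phosphorylation list only 0.16% of 10000 random lists matched on mean expression had a median below its -0.60 (central 95% -0.49 to -0.10). The random lists hold unrelated genes, while members of this list moved together (estimated correlation 0.086). The 0.16% may therefore be too low, and the shift of bright genes is not excluded as the whole cause. For ribosomal proteins 62.6% of the random lists were lower, so their fall is no larger than that of equally bright genes. A change in the RNA content of secreting cells stays open and untested. On RNA quality only the differences between 3' and 5' probe sets of ACTB and GAPDH were compared, and they did not pass (permutation test, adjusted p = 0.0979 and 0.537).

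IFNg_pos 1 carried myeloid transcripts, led by LYZ (13.84), VCAN (11.99), S100A8 (11.08) and TYROBP (10.04). Of 22 measured markers of monocytes and dendritic cells, 1 of which (AIF1) is also in the naive T cell list, 18 were highest in it among IFNg_pos. A rise on that array for any lineage is argued against, since the median of B cell markers exceeded that of the other 7 IFNg_pos libraries by 0.275 and that of platelet and erythroid markers by 0.257, against 3.24 for the myeloid list. RNA of monocytes or dendritic cells in that library may explain it, although the sort for CD25high and CD127neg cells should have removed most of them. No biological explanation was tested.

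Each count was set against 100 splits of the same libraries into groups of the same sizes, the real split included. A split and its mirror are the same, so the real count of higher or of lower genes was set against the larger direction of each other split, whichever it was. With 14 libraries only the real split was as large for the 4273 genes past the threshold, the 2449 higher, the 1824 lower and the 1316 changed at least 2-fold (highest other 2 each). The same held for the 12 lists (highest other 11). The pair numbered 8 had been left out for its IFNG values, which favours the real split, so these splits are no independent test of the labels. With 16 libraries 1 split was as large for the 13 lists (highest other 10). As many as 4 splits were as large for the 17 genes past the threshold (highest other 992), the 17 lower (highest other 696) and the 16 changed at least 2-fold (highest other 258). Such counts from 100 splits are coarse and do not exclude chance. Other splits passed a median of 3 lists with 14 libraries and 4 with 16. For the 0 higher genes the comparison decides nothing, since all 100 splits must give at least as many (highest other 696). The 3 other splits that called more genes than the labels did, 283, 992 and 81, kept 13, 12 and 12 of the libraries numbered 1 to 7 together as labelled and 1, 0 and 0 of the pair numbered 8. They point to a structure of the samples and are no picture of chance.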

How the results depend on the processing

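The fit without the pair numbered 8, and all its alternatives, were chosen only after the 16-library result was seen. With 16 libraries the count of 17 genes (0 up, 17 down, 16 changed at least 2-fold) was unstable. It was 0, with 0 down and 0 changed 2-fold by limma, with the replicate number as a fixed block (3212 genes at an unadjusted p under 0.05), as a random block (3823), and with no filter (4961). It rose to 397 (95 up, 302 down, 242 changed 2-fold) with the mean of a gene's probe sets, where IFNG stayed at 6.08 and passed (adjusted p = 0.0328), to 58 (9 up, 49 down, 54 changed 2-fold) with every probe set on its own, and to 2457 (1129 up, 1328 down, 955 changed 2-fold) with array weights, where IFNG was at 7.08 (adjusted p = 0.00205). Exactly 1 gene was up with the stricter filter, with centred arrays and with a trend and robust prior. Leaving out both libraries numbered 8 gave 4273 (2449 up, 1824 down, 1316 changed 2-fold) and IFNG at 8.04 (adjusted p = 2.68e-08). With a single library left out the count ran from 0 to 1840, with 0 to 852 up, 0 to 1021 down, 0 to 793 changed 2-fold, IFNG from 5.73 to 7.11 and 9 to 13 lists. It was 1840 without IFNg_neg 8, 1687 without IFNg_pos 8 and 3 without IFNg_pos 1, and 0 by limma without any of the others (3327 to 4201 unadjusted). IFNG passed only without IFNg_neg 8 (adjusted p = 0.00234) or IFNg_pos 8 (adjusted p = 0.00682) among these. Of the 13 lists, quantile normalization again left a count of 7 and an estimated correlation 0. The self-test with 1 exchanged pair lost nearly all calls as well, but it changed only 100 genes of each size, far fewer than passed without the pair here. Its loss therefore does not measure the loss in these data. The cause of the other changes was not tested.

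With 14 libraries the counts were steadier, from 2998 to 4999 with a single library left out (1652 to 3079 up, 1344 to 1920 down, 1020 to 1414 changed 2-fold, IFNG 7.81 to 8.21, 10 to 13 lists). What a replicate number marks stays open, because the labels do not say. For that reason the planned fit had no pairs, and the fit of 14 libraries kept this form. Only 4 of 7 correlations of same-numbered deviations were over 0.1 (0.079 to 0.165). Yet all 7 were highest with their own number, while the highest with another number was at most 0.052. This argues for some pairing by number, which the main fit ignores. With 16 libraries 2 of 8 were over 0.1 and 4 highest with their own. The fixed replicate block gave 3484 genes (3154 shared) with 49.2% up against 57.3%, and the random block 5225. Among named genes the fixed block ended the call of 9 and gave 1 a call, while the random block gave 3 a call. No list call changed with the fixed block. Over the other alternatives the share up ran from 47.2% with centred arrays and 49.7% with the stricter filter to 62.2% with no filter and 67.1% with quantile normalization again (2554 up, 1255 down). With every probe set on its own 2031 genes changed at least 2-fold, 2 lists passed with an estimated correlation, and 19 with fry, which does not compare a list with other genes. GINS2, which rose, turned to -0.0193 with the mean of its probe sets, of which the other 2 stood at -0.30 and -0.17. No list that passed changed direction under any alternative run. List calls that an alternative ended stand beside those lists. Without IFNg_neg 6 B cell markers passed (0.0351). With fry, the Th1 (0.0256), Tfh (0.0465), immediate early (0.032), B cell (0.00596), NK and CD8 (0.000771) and platelet and erythroid (0.000771) lists gained an upward call. The PI3K AKT mTOR (0.00118) and coinhibitory (0.0402) lists gained a downward call with fry. Lists gained a call with no filter (PI3K AKT mTOR 0.012, B cell 0.0274, platelet and erythroid 0.0166), the stricter filter (immediate early, B cell, and platelet and erythroid 0.0443 each, NK and CD8 0.0474), the mean of probe sets (B cell 0.0169) and quantile normalization again (immediate early 0.0399). Of the 105 named genes called, 83 passed with each library left out in turn. BLK, MKI67, GINS2, NSDHL, TOX, CD27, CTSW, SLC2A3, GADD45B, NFKBID, NFATC1, ATF3, MYB, NCAM1, NCR1, ALAS2, ITGA2B, IL21, LRRC32, AHR, CISH and IL1RL1 missed the threshold at least once, from 2 times (CTSW, IL21) to 12 times (BLK, NFATC1). Over the other alternatives named genes kept their side of the threshold in 1229 comparisons, lost it in 47 and gained it in 16. Camera has no version with a random block, and the deposited table with unmapped columns was not run as a source of values. Signal near background limits the dim genes, where small rises were most frequent.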

Other observations

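The fit of 14 libraries behind these values was chosen after the result of all 16 was seen. Genes of metabolism, division and survival showed small groups of opposite changes. In apoptosis and survival (adjusted p = 0.356), FASLG (1.60) was the 1 of 27 that rose, 2 fell, XIAP (-1.57) among them, and 24 did not pass, with 1 up and 2 down adjusted over the list alone. In glycolysis (adjusted p = 0.535), HK2 (0.83) and PFKP (0.66) were the 2 of 23 that rose, 3 fell, HIF1A (-0.66) among them, and 18 did not pass, with 2 up and 3 down adjusted over the list alone. Its median (0.00) was upward and its mean (-0.05) and test downward. In the cell cycle list (adjusted p = 0.504), 3 of 27 rose, MKI67 (0.48) among them, CCNE2 (by at least 1.36, with the values of 5 of 7 IFNg_pos libraries below the cutoff of 3.792 raised to it) and MCM5 (-0.95) fell, and 22 did not pass, with 0 up by limma (4 at an unadjusted p under 0.05) and 2 down adjusted over the list alone. Its median (0.11) was upward and its mean (-0.19) and test downward. In heat shock and handling stress (adjusted p = 0.356), BAG3 (1.26) and GADD45B (0.90) were the 2 of 17 that rose, 3 fell, DNAJB4 (-1.62) and DNAJB1 (-1.48) among them, and 12 did not pass, with 2 up and 3 down adjusted over the list alone.

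Of the probe sets without a usable gene symbol, 6968 were tested, and 1331 passed without number 8, with 983 up and 348 down, against 18 in all 16 libraries. Of the 5221 genes with a called probe set when every probe set was tested on its own, 33 had called probe sets of opposite sign. Libraries labelled IFNg_neg 1 to 7 were more alike (median correlation between arrays across genes 0.968, 21 pairs) than IFNg_pos 1 to 7 (0.869, 21 pairs). The bacterial control median was 3.267 ± 0.117 (SD, n = 7) in IFNg_pos and 3.097 ± 0.0429 in IFNg_neg (exact permutation p = 0.00175, adjusted over 7 array measures 0.00306). The 25th percentile of the array was higher and the 75th percentile and SD were lower in IFNg_pos, each without overlap between the groups (adjusted p = 0.00136 each), and the array median was higher (4.757 against 4.713, adjusted p = 0.0122). The differences between 3' and 5' probe sets of ACTB (adjusted p = 0.0979) and GAPDH (adjusted p = 0.537) did not pass.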
